A study of Homo sapiens with 6 samples.

How the data were processed

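RNA was measured in PC-3 cells kept under GDC-0068 (the resistant line, GDC_R) and in cells carried in parallel with DMSO (control), with 3 libraries per group. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.6 to hg19. The counting tool, the gene models and the strand setting are not given in the sources used here. The deposited fragment count of each gene is a whole number, not normalized, in 1 table per library per the file headers. The deposited FPKM values were made by the authors from each count, the mRNA size and 1 fragment total per library. The deposited score (FPM) is the authors' count scaled by that same total, and was used here only to recover the total. Gene counts summed to 35562400 to 44279078 fragments per library, 5.56% to 5.84% above that total.

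The choice of groups, tests, thresholds, gene lists, named genes and most alternatives was made before the data were examined. FPKM had been assumed as the unit, with an edgeR count test as the stated fallback where counts were present. Counts were present, so edgeR was used. Of 27734 gene rows, 849 rows with 396 repeated symbols were left out, and start positions, which count from 0 in the files, are given here counted from 1. The 13070 genes with a unique symbol and a mean FPKM of at least 1 over the 6 libraries were tested.

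Differences were tested with edgeR 4.0.16 (quasi-likelihood, TMM normalization, group as the only term), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Counts at least 2-fold needed an absolute log2 fold change of at least 1 as well. Normalization factors were 0.985 to 1.008 and the biological coefficient of variation was 7.17%. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. FPKM means carry the SD of 3 libraries, and log2 fold changes the standard error of the edgeR fit. Replicate correlations used log2 counts of the tested genes, scaled by library total and TMM factor.

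Named genes were the 10 largest increases and the 10 largest decreases among genes that passed, with a mean FPKM of at least 5 in the higher group, no overlap between the groups and an approved-looking symbol. AKT1, AKT2 and HDAC1 to HDAC11 were named in any case. Some genes that the rule takes are not reported here. In each list, up to 4 passing members with the largest change and a mean FPKM of at least 5 in the higher group were named, or the most abundant member where none passed. Genes named outside this rule are said to be so.

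The 32 lists were PI3K-AKT-mTOR components, FOXO targets, receptor tyrosine kinases, growth factor ligands, histone deacetylases and sirtuins, HDAC corepressor complexes, histone acetyltransferases and BET proteins, MAPK-ERK output genes, proliferation genes, G1 regulators, epithelial, mesenchymal, luminal prostate and neuroendocrine genes, cholesterol and fatty acid synthesis, glycolysis and hypoxia, interferon-stimulated genes, antigen presentation, NF-kB and inflammatory cytokines, the integrated stress response, the unfolded protein response, the BCL2 family, drug efflux transporters, NRF2 targets, lysosome and autophagy genes, YAP-TEAD targets, cytosolic ribosomal proteins, leukocyte markers, endothelial and fibroblast markers, replication-dependent histones, and mitochondrially encoded genes. Of the mitochondrial list, 0 members are under its symbols in the tables, so no test was possible. The 2 lists of other cell types had too few tested members for camera.

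Alternatives were DESeq2 1.42.0, limma-trend on log2(FPKM) with pseudocounts of 0.5, 1 and 0.1, other filters, RLE and quantile normalization, limma without trend, array weights, a replicate block, each library left out in turn, an estimated inter-gene correlation, and the fry rotation test. Normalization by library totals, a GC correction, the GC correction without control replicate 1, and the counts of list members with each library left out were added after the data were seen. The GC correction used loess offsets (span 0.3) on transcript GC content from GENCODE 29, an annotation of GRCh38 from which no coordinates were taken. Positions were tested per chromosome with camera and in windows of 25 neighbouring genes against 1000 random orders. Intervals are 95% bootstrap intervals from 2000 draws of genes, and do not measure the spread between libraries.

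The pipeline was tested on simulated data with 13070 genes. The edgeR test recovered 48% of 50 genes changed 1.25-fold, 98% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and called 7 of 12870 unchanged genes. Camera called the changed set (adjusted p = 8.70e-31) and 0 of 20 unchanged sets. Simulated genes varied independently and no library had a GC effect, so the simulation cannot show how camera behaves with correlated genes. Only 50 genes were changed at each fold, against 50.2% of genes called in the real data, and all genes shared the common dispersion. The recovery rates may therefore differ in the real data. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.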

Results

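RNA levels were measured by RNA sequencing in PC-3, a human prostate cancer cell line that does not depend on the androgen receptor. Resistant PC-3 cells were kept under GDC-0068 (ipatasertib), an ATP-competitive inhibitor of the AKT kinases, and control cells were carried in parallel with the DMSO vehicle. Each group had 3 libraries of total RNA, from cells at passages 20 to 30 per the labels. The dose and the presence of drug at harvest are not given in the sources used here. The series title links resistance to inhibitors of the PI3K-AKT pathway with histone deacetylases (HDACs) on chromatin, and the comparison asks which RNA levels differ between the resistant and the control line. Summed gene counts were 40552438, 41027296 and 37252408 fragments in control replicates 1 to 3, and 35562400, 44279078 and 40658662 in resistant replicates 1 to 3. Pearson's r across genes was 0.9915 to 0.9969 between control libraries and 0.9967 to 0.9971 between resistant libraries, where genes are not independent replicates. Control replicate 1 stood apart from the other control libraries by GC content: across 12517 genes its log2 deviation had a Spearman's rho of -0.751 with transcript GC. The labels do not say whether the libraries of a group came from separate cultures or separately derived lines. The p-values therefore measure the spread between these samples, which may be technical, and not a spread between independent resistant lines.

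**Figure D1:**
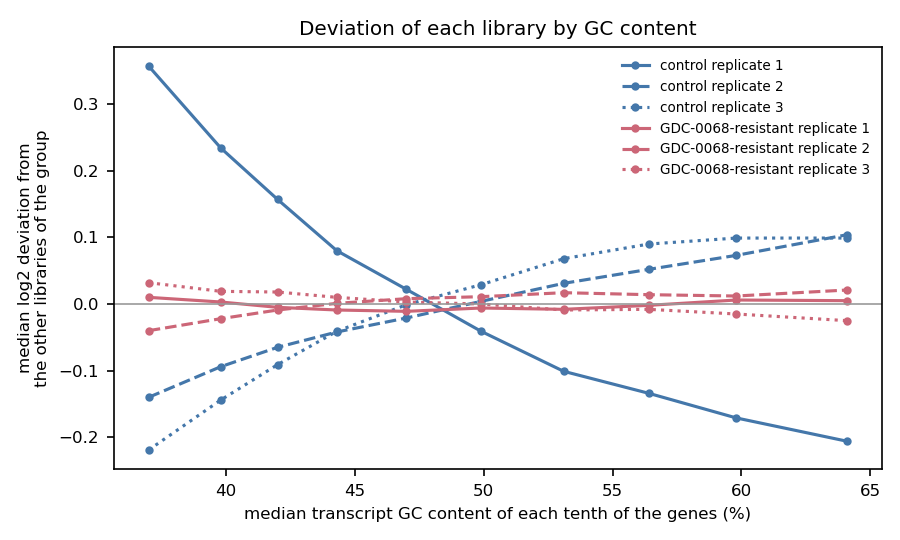
Median log2 deviation of each library from the other libraries of its group (y axis) against the median transcript GC content of 10 equal parts of the genes (x axis, percent), with 1 line per library. Control replicate 1 lies at 0.36 in the part with the lowest GC content and below 0 in the part with the highest.

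Resistant and control cells differed across much of the transcriptome, mostly by less than 2-fold. Of 13070 genes tested, 3200 were higher and 3360 lower in resistant cells, together 50.2%. Among these, 275 genes were higher and 171 lower by at least 2-fold. TGFBI, a secreted matrix protein induced by TGF-beta, and ANKRD1, a target gene of the YAP coactivator, were among the largest increases, and TFF1, a secreted trefoil peptide, and IL13RA2, a decoy receptor for interleukin 13, among the largest decreases. The counts come from edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. Without control replicate 1 they were 4165 higher and 4298 lower, with 298 and 167 at least 2-fold.

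CST1, TGFBI and ANKRD1 were among the 10 largest increases under the naming rule, which needs a mean FPKM of at least 5 in the higher group. CST1, a secreted cysteine protease inhibitor (cystatin SN), rose from 0.418 ± 0.222 FPKM in control to 6.81 ± 0.79 in resistant cells (SD, n = 3 each), a log2 fold change of 4.01 ± 0.25 (SE). TGFBI rose from 0.444 ± 0.0227 to 6.58 ± 0.587 FPKM (log2 fold change 3.87 ± 0.11), and ANKRD1 from 4.82 ± 0.488 to 36.2 ± 1.29 FPKM (2.89 ± 0.08). KRTAP2-3, a keratin-associated protein, rose by a log2 fold change of 2.65 ± 0.13 and NLRP10, of the NOD-like receptor family, by 2.51 ± 0.11. SERPINA1, which encodes the protease inhibitor alpha-1 antitrypsin, rose from 2.39 ± 0.0667 to 13.6 ± 1.09 FPKM (2.48 ± 0.08). PMEPA1, a TGF-beta-induced inhibitor of SMAD signalling, rose from 5.33 ± 0.255 to 28.2 ± 0.484 FPKM (2.38 ± 0.05), and its locus overlaps the noncoding gene NKILA. The metallothionein MT1M and EDN1, the precursor of the vasoconstrictor endothelin 1, each rose by a log2 fold change of 2.32. HIST1H2BE, a histone H2B gene with near-identical copies, had 6, 0 and 1 fragments in control replicates 1 to 3 against 45, 108 and 114 in resistant replicates 1 to 3. Its fitted log2 fold change of 5.13 ± 0.61 became 7.10 without control replicate 1, and fragments shared among H2B copies leave it uncertain. Over these 10 genes the adjusted p of edgeR's quasi-likelihood test (Benjamini-Hochberg) lay between 4.82e-08 and 0.000198.

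TFF1, IL13RA2 and KRT17 were among the 10 largest decreases under the naming rule, which needs a mean FPKM of at least 5 in the higher group. TFF1 fell from 15.7 ± 0.64 FPKM in control to 1.62 ± 0.503 in resistant cells (SD, n = 3 each; log2 fold change -3.26 ± 0.17, SE), and IL13RA2 from 5.50 ± 0.675 to 0.663 ± 0.0723 FPKM (-3.08 ± 0.15). KRT17, a keratin of basal epithelium, fell from 19.6 ± 2.51 to 3.04 ± 0.214 FPKM (-2.70 ± 0.11), and NEFL, the neurofilament light chain, from 56.3 ± 0.906 to 12.8 ± 0.854 FPKM (-2.15 ± 0.06). ALDH3A1, an aldehyde dehydrogenase, and HPGD, which inactivates prostaglandins, fell by 2.32 and 2.09 on the log2 scale. RBP4, the retinol carrier, fell by 2.24 and PRSS35, a serine protease family member, by 2.30 on the log2 scale. NOX5, an NADPH oxidase, had a log2 fold change of -2.32 ± 0.18, and its gene model overlaps SPESP1, so that fragments of the 2 genes may not be separable. HIST1H2BI, another H2B gene with near-identical copies, had a log2 fold change of -2.26 ± 0.16. The adjusted p of these 10 genes in edgeR's quasi-likelihood test (Benjamini-Hochberg) ranged from 1.20e-07 to 1.97e-05.

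**Figure D2:**
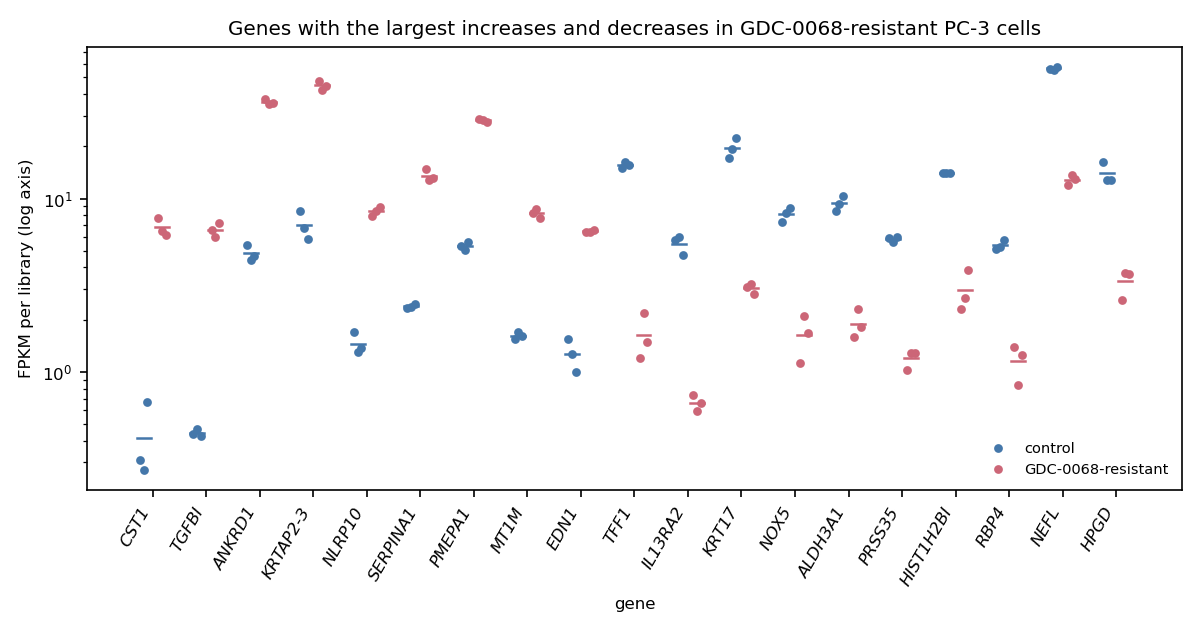
FPKM of each library (points, log axis) and group means (bars) for 9 of the 10 genes with the largest increases and the 10 with the largest decreases. HIST1H2BE is left out because a control library was at 0. Genes were chosen for a mean FPKM of at least 5 in the higher group and no overlap between the groups. By that choice, every resistant library lies on the same side of all control libraries in each gene drawn.

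AKT1, which encodes a kinase that GDC-0068 inhibits, was slightly lower in resistant cells. It fell from 85.3 ± 6.48 to 75.4 ± 1.17 FPKM (SD, n = 3 each; log2 fold change -0.20 ± 0.05, SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0163). That AKT1 call was lost without control replicate 2 or 3 (log2 fold change -0.17 and -0.15) and without resistant replicate 1, 2 or 3 (-0.20, -0.19 and -0.18). The AKT1 call held without control replicate 1 (-0.25) and with a GC correction (-0.22). AKT2, at 23.5 ± 1.56 and 22.5 ± 0.706 FPKM, had a log2 fold change of -0.08 ± 0.05 (edgeR adjusted p = 0.241), and passed without control replicate 1 (-0.13) and with a GC correction (-0.12). AKT1 lies on chromosome 14 at 105235687 to 105262080 (hg19, counted from 1).

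Components of the PI3K-AKT-mTOR pathway more often rose than fell. Among the 31 components tested, 15 rose, 5 fell and 11 did not pass (16 and 5 adjusted over the list alone), with a median log2 fold change of 0.20. The count that fell was 8 without control replicate 1, 1 without resistant replicate 2, and 2 without any other single library. INPP4B, a phosphatase that removes a PI3K lipid product, rose from 8.92 ± 0.842 to 20.3 ± 0.325 FPKM (SD, n = 3 each; log2 fold change 1.16 ± 0.07, SE). SGK1, an AKT-related kinase, rose by a log2 fold change of 1.10 ± 0.06, PIK3CB, the p110-beta catalytic subunit, by 1.09 ± 0.12, and PIM1, a serine-threonine kinase, by 0.94 ± 0.06. The adjusted p of these 4 genes was 3.70e-06 to 0.000155 (edgeR quasi-likelihood, Benjamini-Hochberg). The list was called higher by camera with a preset correlation (Benjamini-Hochberg adjusted p = 0.0169), and adjusted p = 0.372 with an estimated correlation; without a filter on low values the preset value was 0.0804. None of the 9 list calls held with an estimated correlation, where camera called 0 lists and 3 had an unadjusted p under 0.05, while the fry rotation test called 14 lists higher and 7 lower. INPP4B and PIM1 act in different directions on or beside the pathway, so the list's direction is not a direction of signalling.

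Several genes repressed by AKT through FOXO factors were higher. Of 21 tested FOXO target genes, 9 rose, 4 fell and 8 did not pass (10 and 4 adjusted over the list alone), with a median of 0.19, and without resistant replicate 2, 7 rose and 2 fell. CDKN1A, which encodes the CDK inhibitor p21, rose from 5.05 ± 0.411 to 18.4 ± 0.941 FPKM (SD, n = 3 each; log2 fold change 1.85 ± 0.08, SE), and FBXO32, a ubiquitin ligase subunit, from 2.63 ± 0.0562 to 9.31 ± 0.0922 FPKM (1.81 ± 0.05). KLF6, a transcription factor, rose by 0.83 ± 0.06 and INSR, the insulin receptor, by 0.68 ± 0.05. The list did not pass in camera (Benjamini-Hochberg adjusted p = 0.126), and passed among genes with a mean FPKM of at least 5 (adjusted p = 0.0273).

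EGFR, the receptor of epidermal growth factor, rose 2.63-fold, from 18.9 ± 0.786 to 50.3 ± 0.965 FPKM (SD, n = 3 each; log2 fold change 1.40 ± 0.04, SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.21e-07). The Eph receptors EPHB6, EPHB3 and EPHA1 fell, with log2 fold changes of -1.22 ± 0.11, -0.92 ± 0.12 and -0.79 ± 0.08. Of 26 receptor tyrosine kinases tested, 9 rose, 7 fell and 10 did not pass (9 and 8 adjusted over the list alone), and camera did not call the list (Benjamini-Hochberg adjusted p = 0.988). Without control replicate 1, 9 rose and 11 fell. Leaving out resistant replicate 1 gave 6 and 7, and leaving out resistant replicate 2 or 3 gave 7 and 7. The balance of that list therefore depends on single libraries of both groups. PDGFRA, chosen after its values were seen and also on the list of fibroblast markers, fell from 3.73 ± 0.0591 to 0.149 ± 0.0237 FPKM (-4.66) and has the lowest log2 fold change of the 13070 genes tested. IGF1R, the insulin-like growth factor receptor and also chosen after its values were seen, rose from 1.33 ± 0.0647 to 4.96 ± 0.274 FPKM. The EGFR model overlaps EGFR-AS1 and the EPHA1 model overlaps EPHA1-AS1, and the counting was not stated to use strand.

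Ligands of these receptors moved both ways. KITLG, the ligand of KIT, fell from 11.01 ± 2.31 to 2.98 ± 0.148 FPKM (SD, n = 3 each; log2 fold change -1.91 ± 0.14, SE), and the EGFR ligand AREG fell from 5.74 ± 0.24 to 2.30 ± 0.0796 FPKM (-1.34 ± 0.08). HBEGF, another EGFR ligand, rose from 11.97 ± 0.219 to 29.6 ± 0.955 FPKM (1.28 ± 0.05), and PDGFB rose from 8.54 ± 0.76 to 19.7 ± 0.583 FPKM (1.19 ± 0.07). Of 20 ligand genes tested, 9 rose, 6 fell and 5 did not pass (10 and 6 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.403). Among 19 output genes of MAPK-ERK signalling, 8 rose, 4 fell and 7 did not pass (8 and 5 adjusted over the list alone; camera adjusted p = 0.536), with 9 and 7 without control replicate 1. Of these, the feedback phosphatase DUSP5 (0.88 ± 0.05) and HMGA2 (0.70 ± 0.10) rose, while the feedback inhibitor SPRY4 (-0.99 ± 0.07) and the transcription factor ETV1 (-0.72 ± 0.07) fell.

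Among the HDAC genes, those of class IIa and IIb rose where they changed, and the class I genes that changed fell. HDAC9, on chromosome 7 at 18126565 to 19042037, rose 3.13-fold, from 1.51 ± 0.132 to 4.79 ± 0.169 FPKM (SD, n = 3 each; log2 fold change 1.64 ± 0.07, SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.35e-06). HDAC6, a mainly cytoplasmic tubulin deacetylase, rose from 7.99 ± 0.57 to 12.3 ± 0.287 FPKM (0.60 ± 0.06), HDAC7 from 16.8 ± 1.17 to 23.3 ± 0.302 FPKM (0.46 ± 0.06) and HDAC5 from 5.50 ± 0.66 to 7.15 ± 0.312 FPKM (0.36 ± 0.09). HDAC2 fell from 24.8 ± 1.19 to 21.2 ± 0.35 FPKM (-0.25 ± 0.05) and HDAC3 from 35.3 ± 1.59 to 30.6 ± 0.903 FPKM (-0.23 ± 0.05). With a GC correction, HDAC2 was at -0.15 and HDAC3 at -0.27, and both still passed. HDAC8 fell from 8.78 ± 0.249 to 7.68 ± 0.369 FPKM (-0.21 ± 0.06), a call that was lost without control replicate 3 (-0.18) and without resistant replicate 2 or 3 (-0.17 and -0.22), and with a GC correction (-0.14). The adjusted p of edgeR's test was 0.0679 for HDAC1 (91.4 ± 6.98 and 83.9 ± 2.73 FPKM), 0.626 for HDAC4 (2.83 ± 0.181 and 2.96 ± 0.0695 FPKM), 0.160 for HDAC10 (2.33 ± 0.319 and 2.70 ± 0.0101 FPKM) and 0.105 for HDAC11 (9.60 ± 0.801 and 8.77 ± 0.105 FPKM). HDAC1 and HDAC11 passed without control replicate 1 (-0.20 and -0.21) and with a GC correction (-0.17 and -0.18). The HDAC7 model overlaps SLC48A1.

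**Figure D3:**
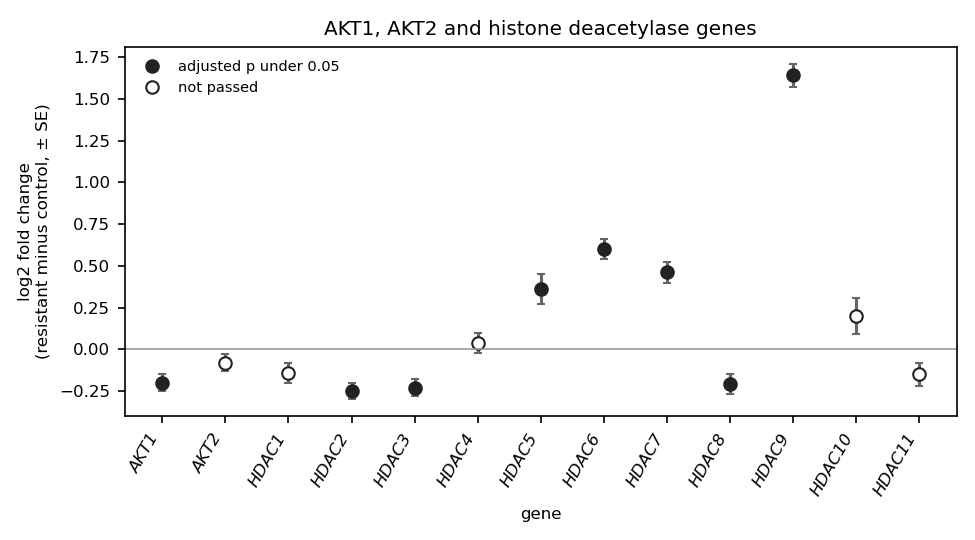
Log2 fold change (resistant minus control, y axis) with its standard error for AKT1, AKT2 and the histone deacetylase genes, from 3 libraries per group. Filled points passed at an adjusted p under 0.05, and HDAC9 lies highest, at 1.64.

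With the sirtuins included, 4 of 18 tested deacetylase genes rose, 4 fell and 10 did not pass, both over all genes and adjusted over the list alone, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.988). Without control replicate 1, 4 rose and 7 fell. SIRT3, the mitochondrial sirtuin, had a log2 fold change of -0.51 ± 0.09 (SE, n = 3 per group), and its gene model overlaps RIC8A. Subunits of HDAC corepressor complexes mostly fell: of 28 tested, 2 rose, 15 fell and 11 did not pass (2 and 15 adjusted over the list alone), with a median of -0.18. Without control replicate 1, 5 rose and 16 fell, and without control replicate 2 or any resistant library, 1 rose and 10 to 13 fell. TBL1X fell from 22.5 ± 0.552 to 15.9 ± 0.698 FPKM (SD; -0.52 ± 0.05), SAP30 from 12.4 ± 0.735 to 8.95 ± 0.815 FPKM (-0.49 ± 0.09) and SAP18 from 59.7 ± 3.41 to 47.5 ± 0.597 FPKM (-0.35 ± 0.05). SAP18 lies on chromosome 13 between CRYL1 and CDK8, in a window of 25 neighbouring genes with a median of -0.44. TBL1XR1 had a log2 fold change of -0.52 ± 0.15, which was -0.28 without control replicate 1. The TBL1XR1 call was lost without resistant replicate 1 (-0.51) or 2 (-0.48). The corepressor list did not pass in camera (Benjamini-Hochberg adjusted p = 0.0799), and passed without a filter on low values (adjusted p = 0.00504). Of 17 histone acetyltransferase and BET genes tested, 8 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone (camera with Benjamini-Hochberg adjusted p = 0.466), and 8 rose and 4 fell without control replicate 1. The acetyltransferase KAT6A rose by a log2 fold change of 0.29 ± 0.05, while HAT1, which acetylates newly made histone H4, fell from 70.9 ± 4.08 to 52.0 ± 1.22 FPKM (-0.47 ± 0.06). EP300 rose by 0.29 ± 0.08, a call lost without resistant replicate 3 (0.20).

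All 21 tested members of the list of replication-dependent histone genes fell in resistant cells, with a median log2 fold change of -0.53. Among all 52 tested genes with a unique HIST symbol, 49 fell and 1, HIST1H2BE, rose, while HIST1H3E (0.01 ± 0.10) and HIST2H2BA (-0.03 ± 0.13) did not pass. HIST2H2AA3 and HIST2H2AA4, left out for a repeated symbol, had 1, 134 and 13 fragments in control replicates 1 to 3 against 401, 82 and 2293 in resistant replicates 1 to 3. HIST1H2BG fell from 930.7 ± 12.4 to 593.4 ± 13.9 FPKM (SD, n = 3 each; -0.67 ± 0.04, SE), HIST1H3H from 809.1 ± 84.1 to 509.7 ± 5.91 FPKM (-0.69 ± 0.07) and HIST2H2AC from 454.1 ± 21.9 to 256.5 ± 24.5 FPKM (-0.84 ± 0.07). HIST1H2BJ fell from 612.1 ± 31 to 355.7 ± 60.5 FPKM (-0.80 ± 0.10). The counts were the same adjusted over the list alone, and camera called the list lower (Benjamini-Hochberg adjusted p = 2.40e-09; adjusted p = 0.372 with an estimated correlation). Most transcripts of such genes lack a poly(A) tail, and copies are near-identical, so single members are uncertain. Of 13 other RNAs without a poly(A) tail that have their own genes, a set chosen after values were seen, 1 rose and 4 fell, with a median of -0.25, while 144 such RNAs mostly within host introns had a median of -0.004.

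Proliferation genes were not called as a set. Of 40 tested, 7 rose, 10 fell and 23 did not pass (7 and 10 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.589). The count that fell was 17 without control replicate 1 and 6 without resistant replicate 2. GINS2, a subunit of the replicative helicase complex, fell from 68.1 ± 3.35 to 46.7 ± 1.23 FPKM (SD, n = 3 each; log2 fold change -0.56 ± 0.05, SE), RRM1, the large ribonucleotide reductase subunit, from 99.4 ± 1.5 to 73.2 ± 0.624 FPKM (-0.46 ± 0.04), and the mitotic kinase CDK1 from 119.0 ± 11.8 to 95.8 ± 4.85 FPKM (-0.33 ± 0.08). The mitotic kinase AURKA rose from 108.3 ± 2.82 to 140.4 ± 2.46 FPKM (0.36 ± 0.04). Among 15 G1 regulators, 4 rose, 4 fell and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.589), and 7 rose and 5 fell without control replicate 1. Besides CDKN1A, CCND1 (cyclin D1) rose from 306.4 ± 5.62 to 424.2 ± 3.38 FPKM (0.45 ± 0.04), while CDKN2C, a CDK4 and CDK6 inhibitor, fell by 0.59 ± 0.06. RB1, the retinoblastoma gene, had a log2 fold change of -0.59 ± 0.13 with all libraries and -0.40 without control replicate 1. RB1 lies on chromosome 13, where the 232 tested genes had a median of -0.214 with all libraries.

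Most YAP-TEAD target genes rose. Of 23 tested, 18 rose, 2 fell and 3 did not pass, with the same 18 and 2 adjusted over the list alone, and the median log2 fold change was 0.52. Besides ANKRD1, CYR61 rose from 37.8 ± 2.64 to 146.6 ± 5.41 FPKM (SD, n = 3 each; 1.94 ± 0.06, SE) and CTGF from 10.0 ± 0.886 to 30.1 ± 0.883 FPKM (1.57 ± 0.07), both secreted matrix-associated proteins. AMOTL2, an angiomotin family member that binds YAP, rose from 13.9 ± 0.9 to 30.9 ± 0.35 FPKM (1.13 ± 0.05). As a set, these targets were called higher by camera (Benjamini-Hochberg adjusted p = 1.43e-06; adjusted p = 0.253 with an estimated correlation).

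NF-kB and inflammatory cytokine genes more often rose than fell: 15 of 24 tested rose, 5 fell and 4 did not pass (16 and 5 adjusted over the list alone), with a median of 0.57. The count that fell was 3, 2 and 2 without resistant replicate 1, 2 or 3. IL6, the interleukin 6 gene, rose from 3.26 ± 0.661 to 11.7 ± 0.628 FPKM (SD, n = 3 each; 1.82 ± 0.13, SE), and CSF2, which encodes GM-CSF, from 1.58 ± 0.415 to 6.63 ± 0.412 FPKM (2.06 ± 0.17). RELB, an NF-kB subunit, rose from 2.23 ± 0.19 to 8.23 ± 0.491 FPKM (1.86 ± 0.09) and BIRC3, an NF-kB-induced inhibitor of apoptosis, from 1.65 ± 0.379 to 6.25 ± 0.251 FPKM (1.90 ± 0.14). The adjusted p of these 4 genes was 2.03e-06 to 2.71e-05 (edgeR quasi-likelihood, Benjamini-Hochberg). Camera called the list higher (Benjamini-Hochberg adjusted p = 0.00103; adjusted p = 0.372 with an estimated correlation).

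Antigen presentation genes mostly rose, with 12 of 15 tested rising, 1 falling and 2 not passing, the same adjusted over the list alone, and a median of 0.45. The class I genes HLA-B, HLA-E and HLA-C rose by log2 fold changes of 0.70 ± 0.06, 0.54 ± 0.04 and 0.53 ± 0.06 (SE, n = 3 per group), HLA-B from 20.1 ± 0.781 to 33.1 ± 2.18 FPKM (SD). ERAP1, which trims peptides for class I molecules, rose by 0.51 ± 0.06, and its gene model overlaps CAST. HLA genes are polymorphic and similar to each other, so the split of fragments among them is uncertain. The antigen presentation list was called higher by camera (Benjamini-Hochberg adjusted p = 0.000332; adjusted p = 0.253 with an estimated correlation). Interferon-stimulated genes went both ways: of 36 tested, 11 rose, 16 fell and 9 did not pass (13 and 18 adjusted over the list alone; camera adjusted p = 0.536). IFI44 (-1.53 ± 0.16), IFIT1 (-1.10 ± 0.07), OASL (-0.93 ± 0.10) and IFITM1 (-0.76 ± 0.14) fell, IFIT1 from 11.5 ± 0.79 to 5.46 ± 0.304 FPKM.

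Most glycolysis and hypoxia genes fell: of 32 tested, 2 rose, 22 fell and 8 did not pass (2 and 23 adjusted over the list alone), with a median of -0.39. HK2, the hexokinase of the first glycolytic step, fell from 20.7 ± 0.324 to 10.8 ± 0.411 FPKM (SD, n = 3 each; -0.96 ± 0.05, SE), P4HA1, a collagen prolyl hydroxylase induced by hypoxia, from 116.2 ± 9.27 to 63.6 ± 0.61 FPKM (-0.89 ± 0.06), and NDRG1 from 70.6 ± 5.82 to 36.6 ± 1.73 FPKM (-0.97 ± 0.06). DDIT4, an inhibitor of mTORC1 induced by stress, fell from 8.77 ± 1.13 to 3.55 ± 0.134 FPKM (-1.32 ± 0.11). Glycolysis and hypoxia genes were called lower by camera (Benjamini-Hochberg adjusted p = 7.08e-06; adjusted p = 0.372 with an estimated correlation).

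Most NRF2 target genes, which serve redox defence, fell as well. Of 21 tested, 2 rose, 14 fell and 5 did not pass, the same adjusted over the list alone, with a median of -0.29. NQO1, a quinone reductase, fell from 111.7 ± 1.09 to 62.2 ± 0.91 FPKM (SD, n = 3 each; -0.87 ± 0.04, SE), GSR, glutathione reductase, from 37.7 ± 1.99 to 20.3 ± 0.684 FPKM (-0.92 ± 0.05), and ME1, the cytosolic malic enzyme, from 22.6 ± 1.64 to 11.8 ± 0.48 FPKM (-0.96 ± 0.07). TRIM16, a ubiquitin ligase, fell by 0.98 ± 0.07. Camera called the list lower (Benjamini-Hochberg adjusted p = 0.00149; adjusted p = 0.372 with an estimated correlation).

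Lysosome and autophagy genes rose in 15 of 33 tested, fell in 3 and did not pass in 15, the same adjusted over the list alone, with a median of 0.14. GABARAPL1, an autophagosome protein, rose from 5.54 ± 0.201 to 15.2 ± 0.962 FPKM (SD, n = 3 each; 1.44 ± 0.08, SE), and ATG14, a subunit of an autophagy lipid kinase complex, from 10.9 ± 0.958 to 21.4 ± 0.607 FPKM (0.96 ± 0.07). WIPI1, an autophagy protein whose gene model overlaps PRKAR1A, rose by 1.08 ± 0.06 and the lysosomal protease CTSF by 0.94 ± 0.08. Camera called the list higher (Benjamini-Hochberg adjusted p = 0.0169; adjusted p = 0.564 with an estimated correlation). That call was lost without control replicate 1, the library that stood apart by GC content (camera adjusted p = 0.0959), when 16 rose and 8 fell.

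Stress and lipid pathways were not called as sets. Of 28 genes of the integrated stress response, 12 rose, 5 fell and 11 did not pass (camera with Benjamini-Hochberg adjusted p = 0.256). STC2, the glycoprotein stanniocalcin 2, rose from 40.6 ± 1.25 to 109.4 ± 2.21 FPKM (SD, n = 3 each; log2 fold change 1.41 ± 0.04, SE), NUPR1, a stress-induced nuclear protein, from 13.9 ± 1.11 to 31.3 ± 2 FPKM (1.15 ± 0.08), and GDF15, a stress-induced cytokine, from 7.03 ± 1.01 to 13.5 ± 0.355 FPKM (0.92 ± 0.10), while DDIT4, also on this list, fell by 1.32 ± 0.11. Of 21 genes of the unfolded protein response, 4 rose, 6 fell and 11 did not pass (camera adjusted p = 0.589), with 3 falling without resistant replicate 2, and with PDIA4, a disulfide isomerase, falling from 156.7 ± 8.72 to 115.0 ± 3.48 FPKM (-0.47 ± 0.05) and CRELD2 falling by 0.54 ± 0.09, while HERPUD1 rose by 0.26 ± 0.05. Among 25 genes of cholesterol synthesis and uptake, 6 rose, 4 fell and 15 did not pass (camera adjusted p = 0.988). The count that fell was 7 without control replicate 1, 2 without control replicate 3 or resistant replicate 1 or 2, and 1 without resistant replicate 3. SREBF2, a transcription factor of cholesterol synthesis, rose by 0.36 ± 0.07, and FDFT1, squalene synthase, fell by 0.28 ± 0.06. Of 21 fatty acid synthesis genes, 7 rose, 7 fell and 7 did not pass (7 and 8 adjusted over the list alone; camera adjusted p = 0.873), with ME1 falling by 0.96 ± 0.07, SREBF1, a lipogenic transcription factor, by 0.67 ± 0.11 and ACACA, acetyl-CoA carboxylase, rising by 0.49 ± 0.04. In the other 3 of these lists, the counts were the same adjusted over the list alone.

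Apoptosis and efflux genes were not called as sets. Of 15 BCL2 family genes, 5 rose, 3 fell and 7 did not pass (camera with Benjamini-Hochberg adjusted p = 0.536). The count that rose was 2 without control replicate 2 or resistant replicate 1, and 3 without resistant replicate 2 or 3. BNIP3, a hypoxia-induced member, fell from 25.3 ± 3.7 to 18.2 ± 1.17 FPKM (SD, n = 3 each; log2 fold change -0.50 ± 0.11, SE), and the pro-apoptotic BAK1 and BOK fell by 0.37 ± 0.07 and 0.41 ± 0.08. BIK, also pro-apoptotic, rose by 0.51 ± 0.14, a call lost without control replicate 2 (0.43) or resistant replicate 1 (0.46). Of 11 drug efflux transporters, 7 rose, 3 fell and 1 did not pass (camera adjusted p = 0.283), and ABCC3, an organic anion exporter, rose from 9.24 ± 0.557 to 16.3 ± 0.154 FPKM (0.80 ± 0.05). ABCC10 rose by 0.52 ± 0.08 and ABCA3 by 0.41 ± 0.10. ABCA1, a cholesterol exporter chosen after its values were seen, fell from 2.80 ± 0.23 to 0.615 ± 0.0402 FPKM (-2.21 ± 0.09), the largest change in that list. Both lists had the same counts adjusted over the list alone.

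Epithelial and mesenchymal genes changed in both directions. CDH1, which encodes E-cadherin, fell from 65.2 ± 1.24 to 34.0 ± 0.988 FPKM (SD, n = 3 each; log2 fold change -0.96 ± 0.04, SE), while the keratin KRT7 rose from 621.1 ± 57.8 to 1149 ± 33.7 FPKM (0.87 ± 0.06), the laminin chain LAMB3 from 90.6 ± 8.46 to 170.2 ± 0.932 FPKM (0.89 ± 0.06) and the tight junction gene CLDN1 by 0.84 ± 0.15. Of 32 epithelial genes tested, 7 rose, 13 fell and 12 did not pass (8 and 13 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.454). On the mesenchymal list, TGFBI rose by 3.87 ± 0.11 and the transcription factor SNAI2 rose from 5.13 ± 0.57 to 8.50 ± 0.145 FPKM (0.71 ± 0.09), while fibronectin, FN1, fell from 63.3 ± 3.74 to 33.6 ± 0.526 FPKM (-0.93 ± 0.05). Of 20 mesenchymal genes tested, 7 rose, 8 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.988). Camera's direction for that list was down while its median of 0.05 and mean of 0.13 were above 0.

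Luminal prostate genes fell more often than they rose, without passing as a set. Of 11 tested, 2 rose, 6 fell and 3 did not pass, the same adjusted over the list alone (camera with Benjamini-Hochberg adjusted p = 0.283). HOXB13, a prostate lineage transcription factor, fell from 76.9 ± 6.3 to 40.3 ± 1.05 FPKM (SD, n = 3 each; -0.95 ± 0.06, SE) and STEAP4, a metalloreductase, from 6.06 ± 0.385 to 1.84 ± 0.0907 FPKM (-1.74 ± 0.08), while NDRG1, also on this list, fell and PMEPA1 rose. Of 6 neuroendocrine genes tested, 2 rose, 2 fell and 2 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.591; 1 rose without resistant replicate 1 or 3), and FOXA2, an endoderm transcription factor, fell by 0.64 ± 0.07. Markers of other cell types were mostly below the filter on low values, and too few were tested for camera. Of 17 leukocyte markers, 2 were tested, of which LCP1, an actin-bundling protein also made by carcinoma lines, had a log2 fold change of -0.15 ± 0.04, lost as a call without resistant replicate 2 (-0.14). Of 16 endothelial and fibroblast markers, 4 were tested and 3 fell, while ESAM was at 2.63 ± 0.0638 and 2.69 ± 0.226 FPKM. Without control replicate 1, 2 leukocyte markers fell. In both marker lists the counts of members that rose (0) and fell (1 and 3) were the same adjusted over the list alone.

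Cytosolic ribosomal protein genes more often rose than fell in resistant cells. Of 52 tested, 27 rose, 2 fell and 23 did not pass, the same adjusted over the list alone, with a median of 0.19, and 31 rose and 4 fell without control replicate 1. RPS12 rose by a log2 fold change of 0.61 ± 0.08 (SE, n = 3 per group), RPL12 by 0.58 ± 0.13 and RPS7 by 0.57 ± 0.13. Camera called the list higher (Benjamini-Hochberg adjusted p = 0.000359; adjusted p = 0.542 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, and some models hold small nucleolar RNAs, so single members are uncertain. Beyond the mesenchymal list, camera's direction differed in sign from the median for the deacetylase list (up, median -0.07, mean 0.10) and the fatty acid list (down, median 0.02, mean -0.06), and no call was made for either.

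**Figure D4:**
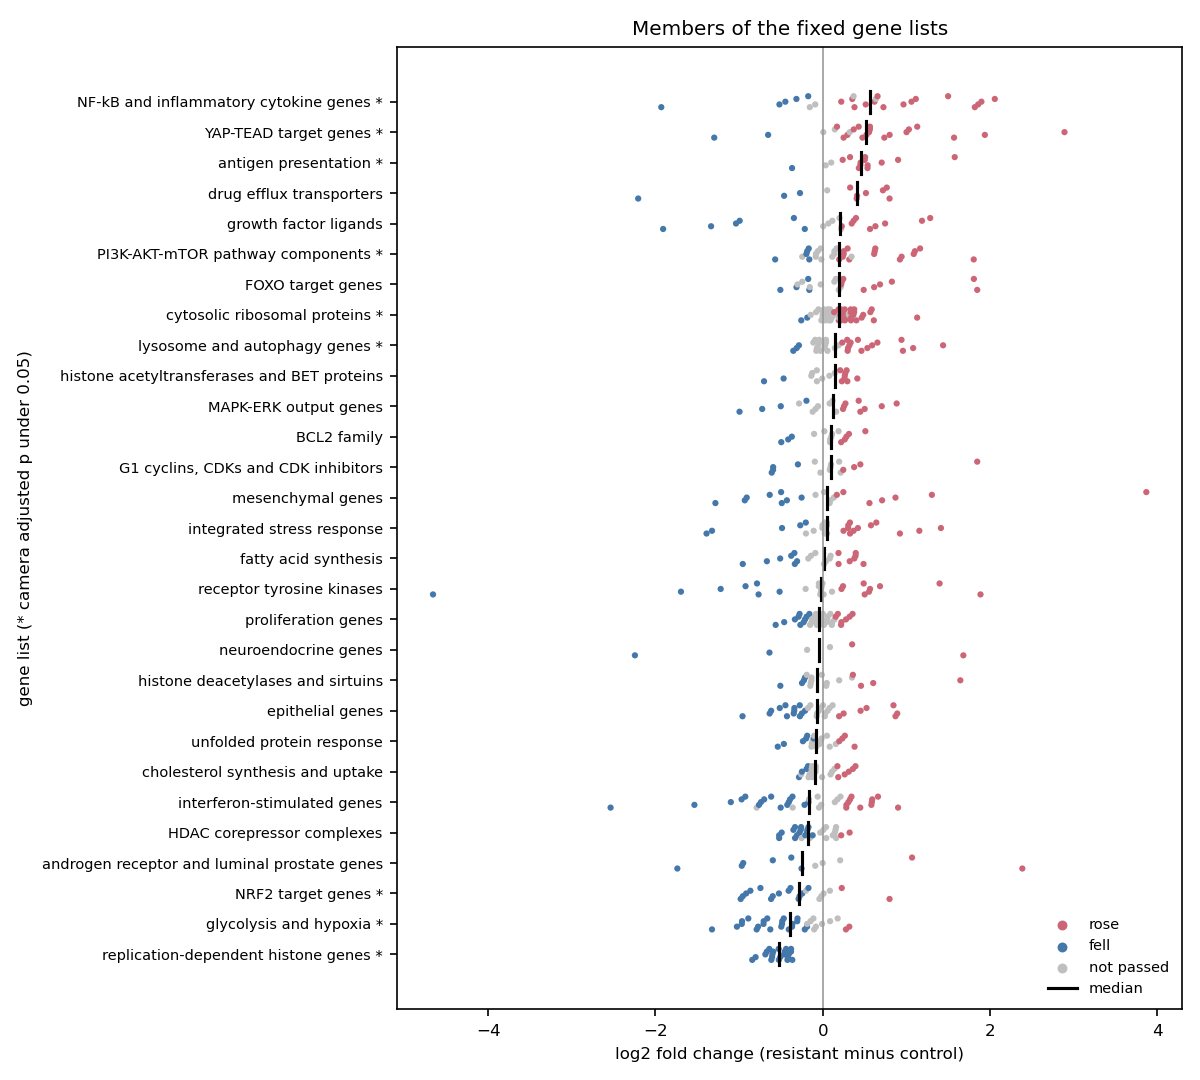
Log2 fold change (resistant minus control, x axis) of each tested member of the 29 gene lists with at least 5 tested members (points), with the list median (bars). Asterisks mark the 9 lists with a camera adjusted p under 0.05 at the preset correlation, and the median lies at 0.52 for YAP-TEAD target genes and -0.53 for histone genes.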

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

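The tests of the GC content and the label of control replicate 1, of RNAs without a poly(A) tail and of the 2 parts of chromosome 13 were chosen after the result was seen. NBPF8, a member of a family of near-identical genes, has a symbol that repeats in the tables and was therefore outside the tests. It had 165, 124 and 106 fragments in control replicates 1 to 3 and 242, 313 and 288 in resistant replicates 1 to 3, a log2 fold change of 1.05. It was singled out because all resistant libraries lay above all control libraries, which chance gives in 10% of genes for 3 against 3 libraries counted both ways. It is 1 of 52 tested rows with a repeated symbol, of which 14 were higher and 7 lower. SNORA105A and SNORA105B, which share 1 position, separated the other way (1261, 828 and 574 against 428, 449 and 475 fragments, log2 fold change -1), as did RNU6-2 (10, 16 and 11 against 7, 2 and 5 fragments, -1.41). Reads shared between copies were not tested. Of 10 splits of the 6 libraries, 1, the real one, gave as many genes (6560 with edgeR, 7466 at an unadjusted p under 0.05, 6479 with DESeq2). The highest of the other splits gave 0 with edgeR, with 21 to 257 genes at an unadjusted p under 0.05 and 0 to 3 with DESeq2. These 10 splits are too few for a share under 0.05.

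Control replicate 1 stood apart from the other control libraries. Its deviation followed transcript GC content (Spearman's rho -0.751 across 12517 genes), so a GC-dependent library effect may account for much of it. A library of the resistant line under the control label is argued against, since the slope of its deviation on the resistant line's fold change within GC bins, 1 for such a library, was 0.051 (0.036 to 0.066). A mixture with a small part of the resistant line cannot be told apart from ordinary variation by that slope. Both the deviation and the fold change subtract the other control libraries, whose shared variation alone pushes the slope above 0. No biological explanation was tested.

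All 21 tested members of the histone list fell, as did 49 of all 52 tested histone genes, of which 1 (HIST1H2BE) rose, and the list had a median of -0.525 (-0.606 to -0.438); HIST2H2AA3 and HIST2H2AA4, at 1 position and outside these 52 for a repeated symbol, were higher (1, 134 and 13 against 401, 82 and 2293 fragments, log2 fold change 4.21), with overlapping groups. Transcript length is argued against, since 342 other coding genes of the same mRNA size had a median of 0.002 (-0.04 to 0.028), and GC content is argued against by the GC-corrected median of -0.555 (-0.638 to -0.466). Lower capture of RNA without a poly(A) tail stays open: 13 such RNAs with their own genes had a median of -0.25 (-0.43 to 0.039). A first form of that test, on 144 RNAs mostly within host introns, had a median of -0.004 (-0.084 to 0.089), which counted against this explanation, and was replaced after its value and those of single RNAs had been seen, since intronic RNAs may carry reads of the host gene; a wider set of 288 intronic RNAs had a median of -0.07 (-0.142 to -0.011). Fewer cells in S phase also stays open, with a median of -0.121 (-0.19 to -0.069) over 31 S-phase genes, and so does a difference between the lines.

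Genes of chromosome 13 were lower, with a median of -0.214 against -0.006 for other genes, 19 of 232 higher and 113 lower, 29 and 123 without control replicate 1 (camera adjusted p = 1.44e-05, adjusted p = 0.934 with an estimated correlation). With an estimated correlation the adjusted p was 0.329 without control replicate 1, 0.0335 with a GC correction and 0.0587 with both, so the call depends on the setting. GC content of control replicate 1 is argued against as the whole cause, since the difference from other genes was -0.175 (-0.222 to -0.141) with a GC correction and without that library. A segment confined to 1 of 2 parts by position, with 116 genes each, is argued against. The part with the smaller difference was at -0.151 (-0.187 to -0.092). A single segment that spans the border of the parts would lower both, so it stays open. A lower copy number of the chromosome in part or all of the resistant cells is a candidate explanation, and DNA was not analysed here.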

How the results depend on the processing

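The GC correction, with and without control replicate 1, and library totals were chosen after the result was seen. Of 80 alternative values of the counts of genes, 72 lay within 1.5 times the reported count. Genes at least 2-fold higher and lower were 152 and 96 with limma-trend on log2(FPKM + 1), 867 and 477 without a filter and 118 and 61 at a mean FPKM of at least 5, where more or fewer genes were tested, and 175 were higher with quantile normalization. Limma with array weights, which did not converge fully, called 5049 genes higher; the cause was not tested. With the replicate block, 3059 genes were higher and 3222 lower, while deviations of same-numbered libraries did not go together (correlations -0.013, 0.048 and -0.088). Leaving out 1 library gave 2540 to 4165 genes higher and 2368 to 4298 lower, with 273 to 298 and 164 to 189 at least 2-fold; 4165 and 4298 were without control replicate 1. It gave 5 to 6 lists higher and 3 to 3 lower. With an estimated correlation camera called 0 lists higher and 0 lower (3 at an unadjusted p under 0.05), and fry, which does not compare with other genes, called 14 higher and 7 lower, among them the mesenchymal list upward (0.000279). Of 608 values of single lists 579 kept the side of the threshold, and where a call was made also the direction. Where neither setting made a call, the direction could differ. Another 15 became weaker, 13 stronger and 1 reversed. Of 2755 values of named genes 2720 stayed the same by this rule, 21 became weaker, 14 stronger and 0 reversed. Leave-one-out ranges were -0.251 to -0.152 for AKT1, -0.131 to -0.048 for AKT2, -0.196 to -0.089 for HDAC1, -0.244 to -0.168 for HDAC8, -0.211 to -0.112 for HDAC11, 0.105 to 0.122 for chromosome 12 and -0.247 to -0.169 for chromosome 13. AKT1 was not called with quantile normalization (-0.103) or limma without trend (-0.173). HDAC8 was not called with the GC correction (-0.141). HDAC1 was called without a filter (-0.173), with array weights (-0.148), with the GC correction (-0.174) and with that correction without control replicate 1 (-0.23). With the same last 3 settings, AKT2 was called at -0.119, -0.121 and -0.122 and HDAC11 at -0.192, -0.176 and -0.183. HDAC10 was called with array weights (0.108). Chromosome 12 was not called without a filter (0.13). For these genes and chromosome 12 the cause was not tested. Depth limits single histone copies such as HIST1H2BE, with 0 to 6 fragments in control libraries.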

Other observations

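The tests of the 5 gene families below and the single genes were chosen after the result was seen, while the tests of chromosomes, windows, TGF-beta response genes and S-phase genes were set before their own result was seen. The families were kept from 23 families of gene symbols looked over in these data, so their p-values, which are also not adjusted, overstate the evidence. All 4 tested metallothioneins rose, MT2A from 260 to 1072 FPKM (log2 fold change 2.02). Of 38 complex I subunit genes 0 rose and 19 fell (median -0.17; camera across n = 38 genes, unadjusted p = 0.000247, and p = 0.0338 with an estimated correlation). Without control replicate 1, 1 rose and 28 fell, and without resistant replicate 2 or 3, 10 fell. Of 37 proteasome subunit genes 3 rose and 21 fell (median -0.17; camera across n = 37 genes, unadjusted p = 0.000859, and p = 0.0205 with an estimated correlation), with 5 and 26 without control replicate 1 and 2 and 16 without resistant replicate 3. Of 7 beta-tubulin genes 0 rose and 5 fell (median -0.50), and of 14 integrin genes 7 rose and 4 fell (median 0.43), with 2 falling without resistant replicate 1 or 2. For the 7 beta-tubulin genes camera gave an unadjusted p = 0.00163, and p = 0.0835 with an estimated correlation. Camera across n = 14 integrin genes gave an unadjusted p = 0.0927, and p = 0.148 with an estimated correlation. The S-phase list had 2 of 31 genes higher and 12 lower, with 5 and 18 without control replicate 1, and 6, 7 and 7 lower without resistant replicate 1, 2 or 3 (camera across n = 31 genes, down, unadjusted p = 0.0124, and p = 0.315 with an estimated correlation).

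THBS1, an adhesive glycoprotein, rose from 166 to 783 FPKM (log2 fold change 2.22) and SNAPC1, a subunit of the small nuclear RNA activating complex, from 55.6 to 252 FPKM (2.16).

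TGFBI and PMEPA1 are TGF-beta response genes, so a hypothesis was that such genes as a set were higher. The 22 TGF-beta response genes tested lay outside the fixed lists and so left out TGFBI and PMEPA1. Of these, 10 rose and 6 fell. Camera across n = 22 genes gave an unadjusted p = 0.304, so that set was not called.

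Chromosome 12 genes were higher, with 252 of 695 rising and 107 falling (median 0.104 against -0.017; camera adjusted p = 0.00527, and adjusted p = 0.251 with an estimated correlation, 0.218 with that and without control replicate 1, 0.0453 with a GC correction, and 0.0587 with both). In windows of 25 genes, 0.001 is the smallest p that 1000 random orders can give. That value was reached by the window from LGALS3 to SIX4 on chromosome 14 at 55595935 to 61190852 (median 0.52, 19 rose and 0 fell), by SNORD102 to RFC3 on chromosome 13 (-0.51) and by a pair of windows of the histone cluster on chromosome 6 (-0.56 and -0.51). On chromosome 17 the window from SNORA50C to BPTF had a median of 0.47 (permutation p = 0.002). A pair of windows on chromosome 12 also passed, ANKRD52 to NXPH4 at 56631591 to 57620232 (0.46, permutation p = 0.002, 17 rose and 2 fell) and PCBP2-OT1 to RDH5 at 53858252 to 56118526 (0.43, permutation p = 0.003, 17 rose and 1 fell). So did CRYL1 to CDK8 on chromosome 13 (-0.44, permutation p = 0.003). With a GC correction and without control replicate 1, SNORD102 to RFC3 was at -0.4 and CRYL1 to CDK8 at -0.38. The pair on chromosome 12 was then at 0.42 and 0.39, and the pair on chromosome 6 at -0.6 and -0.51. The chromosome 14 and 17 windows stayed at 0.52 and 0.47. No permutation p was computed for these corrected medians.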
